A study of Camponotus floridanus with 3 samples.

How the data were processed

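Poly(A) RNA from the whole bodies of 3 Florida carpenter ants, Camponotus floridanus, was sequenced as 3 strand-specific libraries, in which dUTP marks the second cDNA strand. The libraries came from 1 queen and 2 workers. The ants were taken without treatment from laboratory colonies that held a queen. They were kept at 25 °C in cycles of 12 hours of light and dark and were fed 2 times a week. The series text says that 1 of the workers was a major and 1 a minor, which are the large and small worker types of this ant. The labels do not say which worker is which, so the 2 workers form 1 group and are called worker 1 and worker 2 by the replicate numbers of the labels. The labels give all 3 libraries the set number 2. Nothing says whether the ants shared a colony.

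The authors deposited 1 table of RPKM values (reads divided by feature length and by the read total of the library) with a column for each library, per the file headers. STAR 2.5.0b, a read aligner, is named in the submitters' processing notes. The genome build, the annotation, the counting tool and the filters are not given in the sources used here. The table lists 17323 features. Of these, 16704 IDs hold only a number, 457 carry tRNA, 38 rRNA, 28 snRNA and 96 mir. None of the 17323 IDs matched an entry of the RefSeq gene table of assembly Cflo_v7.5 (0 matches), and the deposited table pairs no ID with a gene name. The 22 gene lists fixed by name before the data were examined therefore gave no values, and none is given for corazonin or vitellogenin. Features are named by ID. No coordinates are given.

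RPKM values hold no counts, but the low values of each feature were whole multiples of the value of 1 read. Read totals and feature lengths were recovered from these steps. The ratio of the libraries' totals came from the commonest ratio of low values, and the absolute total from the steps of short tRNA and mir features, whose lengths must be whole numbers. After refinement the totals lay within 0.105 reads of a whole number in each library, at 16914235 for the queen, 6688533 for worker 1 and 13773937 for worker 2. These are the totals by which the deposited values had been divided. For each feature the shortest whole length from 20 to 30000 bases was taken that gave whole reads in every library, within the rounding of the 6 digits printed, and it was kept where fewer than 0.05 chance matches were expected. This gave a length and read counts for 9547 of the 9600 tested features. On 2000 simulated features the true length came back for 92.6%, the true length divided by a common factor for 6.75%, another length for 0% and none for 0.65%. The recovered lengths and reads are inferences from the deposited values. They served for depths, counting intervals and the comparison by length, and no count model was fitted to them. At the median recovered length of 1587 bases, 1 read is worth 0.0373 RPKM in the queen, 0.0942 in worker 1 and 0.0457 in worker 2.

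Features with a mean of at least 1 RPKM over the 3 libraries were tested. The queen was compared with the workers on log2(RPKM + 1) in limma 3.58.1 under R 4.3.3, with a trend of the variance on the level, two-sided tests, and Benjamini-Hochberg adjustment with a threshold of 0.05. Differences on this scale understate the change of low features. The single queen library leaves 1 residual degree of freedom, which comes from the 2 workers. The queen is assumed to vary like them, and the standard errors (SE) and p-values rest on the spread between these workers only. That spread includes any difference between worker types. In data made from the workers' own differences shuffled among the 9600 features, limma called 48 of 50 features raised by 7 on the log2 scale, 11 of 50 raised by 4, 6 of 50 lowered by 7, 0 of 50 lowered by 4, and 0 of 9400 unchanged features. Changes were seeded in features with a mean of at least 4 on the log2 scale. Values under 0 were set to 0, so lowered features could fall by less than stated. The simulated queen had no general shift from the workers, while the real median difference was 1.60. The unchanged features therefore do not give the rate of false calls in the real values. That simulation replaced a first version with normal noise of the workers' spread at each level, after the first had been run. In the first version limma called 0 of the 200 changed features (139 at an unadjusted p under 0.05). The prior degrees of freedom that limma estimated were 5.16 there and infinite with the shuffled differences. On the real values they were infinite in the fit as reported, but 1.99 without a filter, 2.64 after median-of-ratios scaling, 2.35 with that scaling and no trend, and 5.43 after quantile normalization. The smallest p-values rest on the infinite estimate. With it, each SE given for a feature as deposited is the spread between the workers pooled over features of like level. The feature's own spread between the workers has no weight in it. Worker 1 minus worker 2 had a median of -1.49 on the log2 scale as deposited. The shuffled differences keep that shift between the workers, while the normal noise does not. How many true changes the test can find therefore depends on this shift and on the form of the noise, which 2 workers cannot settle. The estimate was finite after median-of-ratios scaling and quantile normalization, which remove the shift, but also without a filter, which leaves it in place. Counts of features in which the queen lay at least 4-fold above the higher worker or below the lower one, and counts of features 4-fold apart between the workers, were taken on the same scale without a test.

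Median-of-ratios scaling divides each library by the median of the ratio to the geometric mean. That median was taken over features above 0 in all 3 libraries with a mean of at least 1 RPKM. Other alternatives were pseudocounts of 0.1 and 5, no filter or a minimum of 5 RPKM, quantile normalization, rescaling to an equal sum without the 20 most abundant features, limma without the trend, robust limma, a minimum change of 2-fold, an adjusted p threshold of 0.1, folds of 2 and 8, and each worker left out. The rule for naming, fixed before the data were examined, took the 2 IDs highest and the 2 lowest in the queen among features past the threshold, ranked by the smaller of the gaps to the 2 workers, and the 5 highest RPKM values of each library. The ID classes, the run of consecutive IDs, the comparison by length and the extremes between the workers were chosen after the data were examined. Medians of ID classes were set against 10000 random lists of the same size matched on level in 20 bins, a description of these libraries. The lists were not matched on feature length. The lists were drawn from all tested features, the class itself included, and again from features with no RNA class in their ID, an alternative added after seeing the data. Intervals on ratios of reads are exact conditional binomial 95% intervals, and a count of 0 was taken as 3 reads. Both cover counting error only and leave out variation between ants and between libraries. Reads made by PCR are not independent molecules, so both can understate the counting error too. Python 3.11.15 with scipy 1.17.1 was used for the rest.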

Results

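Transcript levels were measured in the whole bodies of 1 queen and 2 workers of Camponotus floridanus, an ant in which the queen lays the colony's eggs and workers forage, nurse and defend. The read totals by which the RPKM values had been divided were 16914235 in the queen, 6688533 in worker 1 and 13773937 in worker 2, as recovered from the steps of the values. Features with a recovered length held 8918790 of these reads (52.7%) in the queen, 1265089 (18.9%) in worker 1 and 5165631 (37.5%) in worker 2, so the depth behind most features differed more between the libraries than the totals do. Of the 17323 features, 12339 were above 0 in the queen, 9947 in worker 1 and 12154 in worker 2, and 4113 were at 0 in all 3 libraries. The 9600 features with a mean of at least 1 RPKM were tested. Across these features log2 values of the 2 workers had a Pearson's r of 0.83, while the queen had an r of 0.48 with worker 1 and 0.47 with worker 2. Features are not independent replicates, and these values carry no test.

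The libraries differed in how far a few features filled them. The 20 most abundant features held 22.0% of the RPKM sum in the queen, 70.0% in worker 1 and 40.7% in worker 2. Among tested features the median level was 15.8 RPKM in the queen, 1.42 in worker 1 and 7.31 in worker 2. The median-of-ratios factors were 2.55 for the queen, 0.290 for worker 1 and 1.27 for worker 2. By these factors, the typical tested feature above 0 in all 3 libraries read 8.79-fold higher in the queen than in worker 1. Against worker 2 it read 2.01-fold higher. Over all 9600 tested features the median difference on the log2(RPKM + 1) scale was 2.35 against worker 1 and 0.89 against worker 2. As deposited, the median difference between the queen and the mean of the workers was 1.60 on the log2 scale. Changes are therefore given as deposited and after median-of-ratios scaling, which takes this shift away (median -0.00095).

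A run of 9 IDs with consecutive numbers, Cflo_13844 to Cflo_13852, held most of the highest values and was singled out after its values were seen. It supplied 5 of the 5 highest values in worker 1, 4 of 5 in worker 2 and 1 of 5 in the queen. Single features of the run lay between 481 and 6030 RPKM in the queen, between 2881 and 59501 in worker 1 and between 1712 and 17301 in worker 2. The run made up 7.07% of the RPKM sum in the queen, 43.5% in worker 1 and 19.9% in worker 2. Its 9 features were each lower in the queen than in both workers, by a median of -2.29 on the log2 scale as deposited and -4.36 after scaling, and 0 of the 9 passed the limma test (lowest adjusted p 0.65, and 2 with an unadjusted p under 0.05). The other abundant features were mostly rRNA. Cflo_rRNA18 was at 11443 RPKM in the queen, 10287 in worker 1 and 12274 in worker 2, while Cflo_rRNA14 was at 6421, 22781 and 6815 RPKM and Cflo_rRNA15 at 6255, 18680 and 6211 RPKM in the same order. The remaining numbered feature among the 5 highest of the queen, Cflo_13241, was at 6141, 2306 and 5265 RPKM.

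The comparison of castes asked which transcripts separate a queen from workers. In the limma test on values as deposited, 34 of the 9600 features differed at an adjusted p under 0.05, with 16 higher and 18 lower in the queen, and 677 had an unadjusted p under 0.05. The split moved with the settings: 22 were higher and 53 lower after rescaling without the 20 most abundant features, 125 and 150 after quantile normalization, 100 and 36 with a pseudocount of 0.1, 31 and 13 with a pseudocount of 5, 73 and 39 with a minimum of 5 RPKM, and 98 and 25 without the trend. All 34 lay outside both workers by at least 4-fold, as deposited and after median-of-ratios scaling. Their differences ran from 4.52 to 9.48 on the log2 scale in size. The calls did not hold after median-of-ratios scaling, when limma called 0 features and 1331 had an unadjusted p under 0.05, nor without the filter on low features, when it called 0 of 13210 and 1126 had an unadjusted p under 0.05.

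The 2 named features highest in the queen were nearly silent in the workers. They were picked for their gaps to both workers, a rule that favours such features. Cflo_05659 was at 874 RPKM in the queen against 0.331 ± 0.358 RPKM in the workers (SD, n = 2), a difference of 9.39 ± 2.05 (SE) on the log2 scale with a limma adjusted p of 0.0028. It rested on 41655 reads in the queen, 11 in worker 1 and 3 in worker 2. The queen's value was 1497-fold that of worker 1 (95% interval 837 to 3000) and 11307-fold that of worker 2 (3869 to 54832). Cflo_09871 was at 598 RPKM in the queen, from 7923 reads, against 2 reads in worker 1 and 0 in worker 2. Its difference was 8.99 ± 2.21 (SE) with a limma adjusted p of 0.019, and the queen was at least 2151-fold higher than worker 2, with worker 2 set at 3 reads. After scaling the differences were 7.59 ± 0.945 (SE) for Cflo_05659 and 7.27 ± 0.839 for Cflo_09871, and the limma adjusted p was 0.34 for both. With a pseudocount of 0.1 in place of 1 the limma adjusted p was 0.085 for Cflo_05659 and 0.22 for Cflo_09871, so these calls also end there.

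The 2 named features lowest in the queen were among the abundant transcripts of the workers. This follows from the rule, since gaps so wide need a high level in both workers. Cflo_00610 was at 0.606 RPKM in the queen, from 10 reads, against 1041 RPKM in worker 1 and 1257 in worker 2. The difference was -9.48 ± 1.19 (SE) with a limma adjusted p of 9.7e-12, and the level was 1719-fold the queen's in worker 1 (934 to 3586) and 2075-fold in worker 2 (1128 to 4328). Cflo_02738 was at 9.10 RPKM in the queen, 3257 in worker 1 and 9908 in worker 2, with a difference of -9.14 ± 1.13 (SE) and a limma adjusted p of 6.2e-12. Its level was 358-fold the queen's in worker 1 (304 to 425) and 1089-fold in worker 2 (924 to 1293). After scaling the differences were -10.58 ± 1.59 for Cflo_00610 and -11.00 ± 2.51 for Cflo_02738 (SE), with a limma adjusted p of 0.34 for both.

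**Figure D1:**
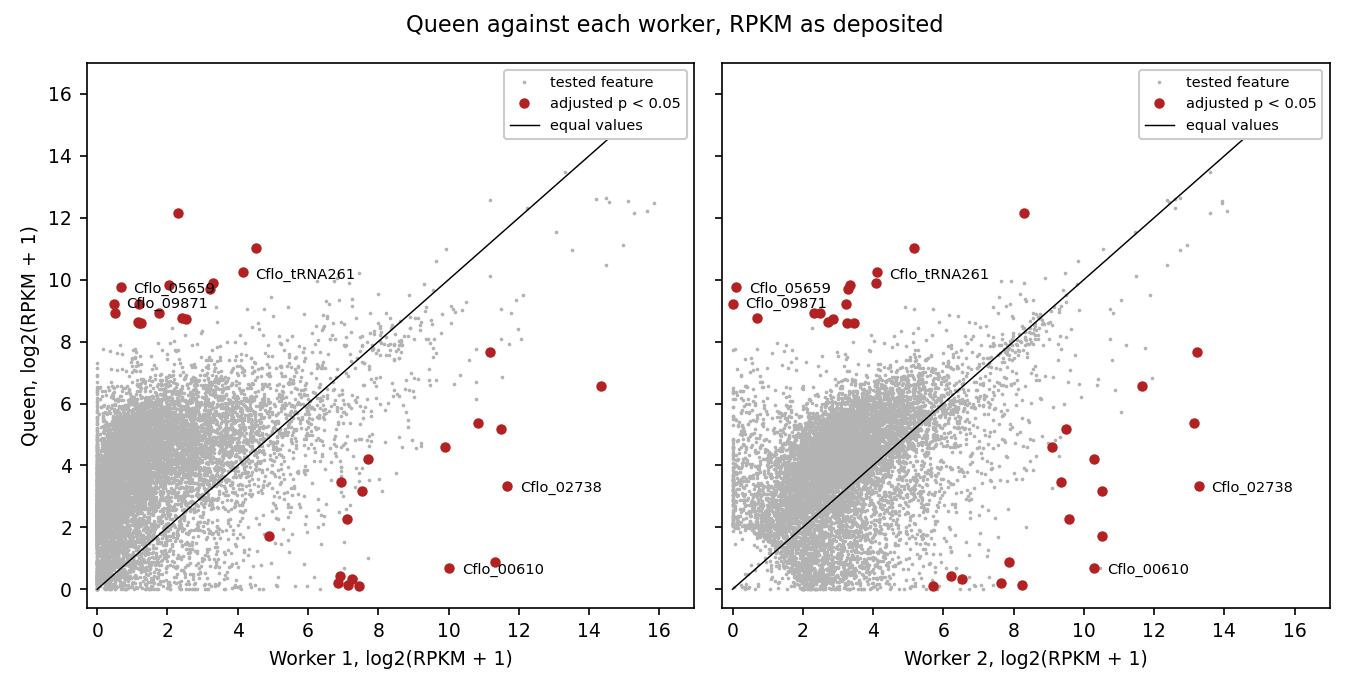
Each point is 1 of the 9600 tested features, with the queen's log2(RPKM + 1) on the vertical axis and that of worker 1 (left) or worker 2 (right) on the horizontal axis, for values as deposited. Red points are the 34 features past the limma threshold, the labelled points are the 4 named features and Cflo_tRNA261, and most grey points lie above the line of equal values in both panels.

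Without a test, 1920 features lay at least 4-fold above both workers in the queen and 210 at least 4-fold below both, as deposited. After median-of-ratios scaling the split was 446 higher and 692 lower, so the excess of higher features turned round. The 446 were all among the 1920, and 207 features were lower under both scalings. Worker 1 and worker 2 weighed differently: against worker 2 alone 1947 features were at least 4-fold higher and 789 lower in the queen, and against worker 1 alone 5494 were higher and 297 lower. By any margin, the queen lay outside both workers in 80.6% of tested features as deposited, with 6601 above and 1137 below, and in 78.9% after median-of-ratios scaling, with 3928 above and 3650 below. For libraries on the same scale chance puts any given library outside the other 2 in 66.7% of features, a value that the shift between these libraries as deposited does not meet. On the level of presence, 151 features at 1 RPKM or more in the queen were at 0 in both workers, and 31 features at 1 RPKM or more in both workers were at 0 in the queen. With a minimum of 10 RPKM these counts were 27 and 4. A 0 allows up to 3 reads, which at the median length is 0.112 RPKM in the queen, 0.283 in worker 1 and 0.137 in worker 2. In shorter features 3 reads are worth more RPKM, so a 0 there need not lie below 1 RPKM. Short features at 1 RPKM may likewise rest on few reads. The lengths and reads of the features in these counts were not examined.

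**Figure D2:**
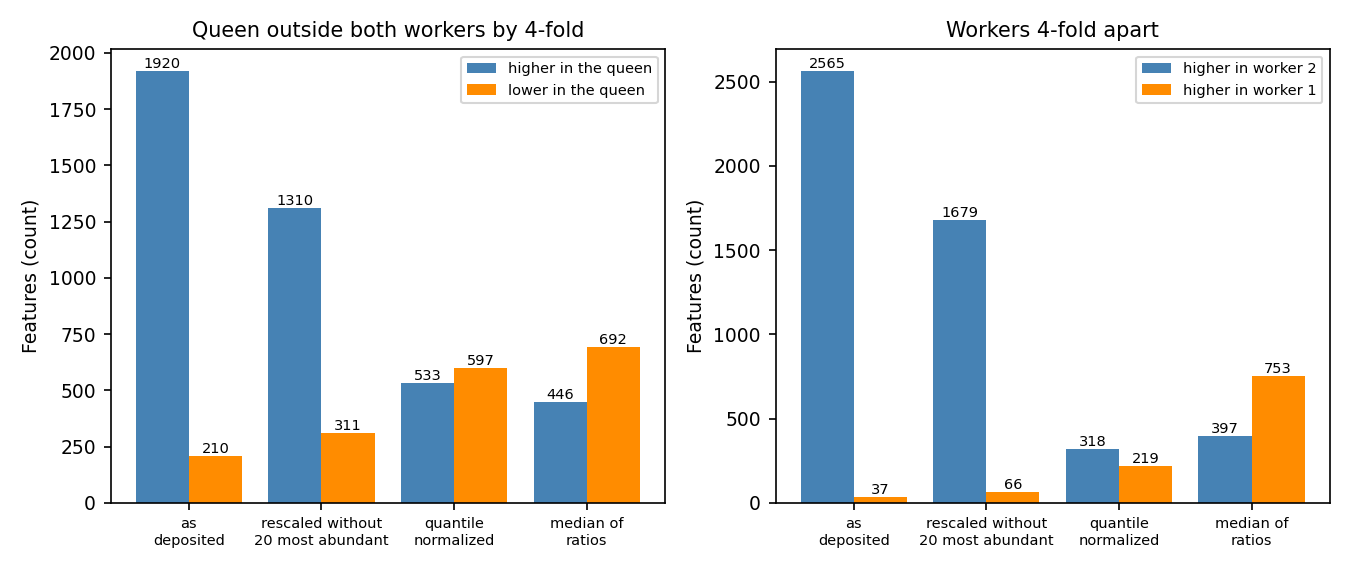
Bars count features under 4 scalings of the same RPKM table, for the queen at least 4-fold outside both workers (left) and for workers at least 4-fold apart (right). The bars for higher in the queen fall from 1920 as deposited to 446 after median-of-ratios scaling, while those for lower in the queen go from 210 to 692.

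Among non-coding classes, as the IDs give them, the medians of tRNA and rRNA features were higher in the queen as deposited and after scaling. The median of snRNA features turned. These values stand against the general shift: the median difference of all 9600 tested features was 1.60 as deposited. Of all tested features, 1920 were at least 4-fold above both workers as deposited and 446 after scaling. Transfer RNAs carry amino acids to the ribosome and, like most rRNA and snRNA, are not polyadenylated as a rule. Poly(A) RNA was sequenced, so reads of these classes may depend on how the poly(A) selection went in each library. That was not measured, and the values need not follow the level of these RNAs in the body. Of 53 tested tRNA features, 18 were at least 4-fold above both workers and 0 below, and after scaling 11 were above and 0 below. Their median difference was 1.93 on the log2 scale and 0.68 after scaling, and the median as deposited lay at percentile 99.98 of random lists matched on level (median of those lists 1.11), and at the same percentile, 99.98, of lists drawn without RNA classes. The lists were not matched on length, and 1 read is worth more RPKM in a short feature. Cflo_tRNA261 had a recovered length of 72 bases, against a median of 1587 over tested features. The percentile therefore does not account for the few reads behind short features. The size of the median depended on the settings: it was 3.18 with a pseudocount of 0.1, 0.85 with a pseudocount of 5, 0.96 after quantile normalization and 0.90 over all 138 tRNA features above 0 when none was filtered out. By the limma test 1 rose, Cflo_tRNA261, at 1203 RPKM in the queen, 16.6 in worker 1 and 16.1 in worker 2 (1465, 8 and 16 reads). Its difference was 6.11 ± 1.28 (SE) with a limma adjusted p of 0.0015, and 4.06 ± 1.39 after scaling with an adjusted p of 0.36.

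Of 25 tested rRNA features, the RNA core of ribosomes, 8 were at least 4-fold above both workers and 0 below as deposited, and 0 were outside by 4-fold after scaling. Their median difference was 1.43 on the log2 scale as deposited, at percentile 99.3 of random lists matched on level (median of those lists 0.31) and at 99.6 of lists drawn without RNA classes (median 0.24), with 18 features above both workers and 1 below, and it was 0.48 after scaling, 2.60 with a pseudocount of 0.1 and 0.71 with a pseudocount of 5. The limma test called 0 of the 25, and 6 had an unadjusted p under 0.05. As deposited the rRNA median lay under that of all 9600 tested features (1.60), of which 6601 were above both workers. After scaling it lay above that of all tested features (-0.00095). Members of the rRNA class went different ways. Cflo_rRNA21 was at 526 RPKM in the queen, 25.9 in worker 1 and 34.8 in worker 2, and Cflo_rRNA24 at 251, 12.0 and 9.68 RPKM. Cflo_rRNA16 was at 5848 in the queen, 24431 in worker 1 and 5528 in worker 2. The rRNA class made up 9.45% of the RPKM sum in the queen, 15.5% in worker 1 and 8.51% in worker 2. Of 19 tested snRNA features, the small nuclear RNAs, 5 were at least 4-fold above both workers as deposited and 2 after scaling, 0 passed the limma test (2 with an unadjusted p under 0.05), and the class median, at percentile 76.3 of random lists as deposited and 77.7 of lists without RNA classes, turned from 1.51 to -0.54 with scaling. Cflo_snRNA9 was at 52.4 RPKM in the queen, 0 in worker 1 and 0.376 in worker 2. Of 96 mir features only 2 had a mean of at least 1 RPKM, and both were lowest in the queen.

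The 2 workers were 1 major and 1 minor in unknown order, so their comparison has no direction by type, no replicate and no test. As deposited, 2602 of the 9600 features were at least 4-fold apart, with 2565 lower and 37 higher in worker 1. After median-of-ratios scaling 1150 were at least 4-fold apart, with 397 lower and 753 higher in worker 1. The 397 and the 37 were in the lists of both scalings. The most extreme features were chosen after their values were seen. Cflo_12858 was at 1.00 RPKM in worker 1 and 1399 in worker 2, from 4 and 11501 reads, with 0.594 RPKM in the queen. Cflo_00597 was at 164 RPKM in worker 1 and 1.97 in worker 2, from 1089 and 27 reads, with 0.297 RPKM in the queen.

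The ratio of the workers changed with feature length. In the 1194 shortest features, of 26 to 542 bases, the median log2 ratio of worker 1 to worker 2 was -1.25 (95% bootstrap interval over features -1.43 to -1.13). In the 1194 longest, from 3735 bases, it was -2.56 (-2.64 to -2.50). Over 9547 features Spearman's rho of length and ratio was -0.29 and Pearson's r was -0.21, with a permutation p of 0.0001 for rho, the smallest that 10000 shuffles can give. The ratio of the queen to worker 2 moved the other way, from 0.62 (0.46 to 0.70) in the shortest to 1.20 (1.07 to 1.30) in the longest features. Its rho with length was 0.11 (permutation p of 0.0001) but Pearson's r was only 0.043. Over 4558 features with a mean of at least 10 RPKM, its rho was 0.19 and Pearson's r was 0.077. These relations are across features, which are not independent replicates, and 4 such relations were computed.

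**Figure D3:**
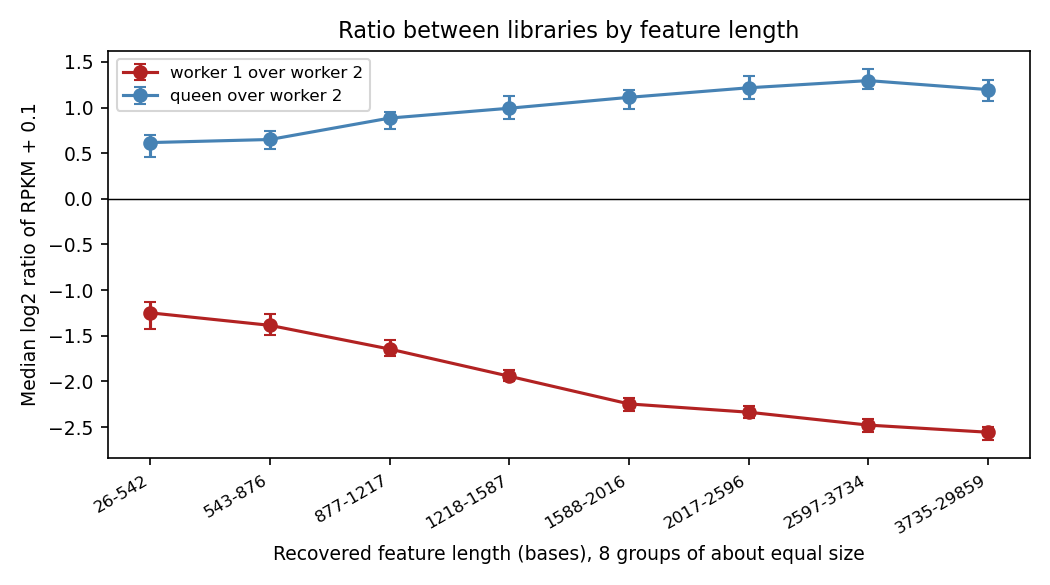
Points are the median log2 ratio of RPKM + 0.1 in 8 groups of tested features by recovered length in bases, for worker 1 over worker 2 (red) and queen over worker 2 (blue), with 95% bootstrap intervals over features. The red points go from -1.25 in the shortest to -2.56 in the longest group, and the blue points from 0.62 to 1.20.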

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

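The fits without RNA classes, the fit with median-of-ratios scaling and no trend, and the alternatives for ID class medians and percentiles were chosen after the data were seen. The 4 named features kept their direction under the 9 alternatives computed for each. The rule that picked them, by their gaps to both workers, largely fixed this. Leaving out a worker, changing the pseudocount or dropping the trend cannot turn a feature that lies outside both workers. Their gaps were also wider than the largest median-of-ratios shift, 3.14 on the log2 scale between the queen and worker 1. The kept direction is therefore no check of the 4 named features, and their calls did not hold throughout. Their limma adjusted p ranged over the alternatives with a test from 3.4e-06 to 0.39 for Cflo_05659, 8.4e-06 to 0.39 for Cflo_09871, 7.0e-16 to 0.39 for Cflo_00610 and 9.9e-12 to 0.39 for Cflo_02738. Limma called 34 features as reported, 136 with a pseudocount of 0.1, 112 with a minimum of 5 RPKM, 275 after quantile normalization, 75 after rescaling without the 20 most abundant features, 123 without the trend and 17 with a minimum change of 2-fold. It called 0 without a filter (1126 at an unadjusted p under 0.05), 0 after median-of-ratios scaling (1331) and 0 with that scaling and no trend (1205). Of the 34, 32 were also called with a pseudocount of 0.1, 33 with the minimum of 5 RPKM and 29 after quantile normalization. Robust limma and the minimum change of 2-fold kept fewer of the 34 than these. The cause of the differences in calls was not tested. The count of features 4-fold outside both workers, 2130, was 918 with a pseudocount of 5, 1138 after median-of-ratios scaling, 1130 after quantile normalization, 4892 at 2-fold and 651 at 8-fold. Leaving out 1 worker gave from 2736 (without worker 1) to 5791 (without worker 2). The share higher in the queen, 90.1%, turned to 39.2% after median-of-ratios scaling and to 47.2% after quantile normalization, was 80.8% (1310 against 311) after rescaling without the 20 most abundant features, which does not centre the ratios, and was 71.2% without worker 1. The 2602 features 4-fold apart between the workers were 5215 and 449 with pseudocounts of 0.1 and 5, 1150 after median-of-ratios scaling, 537 after quantile normalization, 6876 at 2-fold and 475 at 8-fold. The share higher in worker 2, 98.6%, turned to 34.5% after median-of-ratios scaling and was 59.2% (318 against 219) after quantile normalization and 96.2% after that rescaling. The snRNA median turned from 1.51 to -0.54 with median-of-ratios scaling and was 0.50 after quantile normalization. The tRNA median stayed positive, from 0.68 with median-of-ratios scaling to 3.18 with a pseudocount of 0.1, and so did the rRNA median, from 0.48 to 2.60 under the same settings. Features without an RNA class in their ID gave 31 calls. Dropping the filter left both 4-fold counts as they were, since such a change needs more than the minimum. With either worker left out limma has no residual degree of freedom, so those settings gave values only. The planned medians of named gene lists gave no values. No paired analysis was possible with 1 queen. All 3 libraries carry the set number 2, and the queen shares the replicate number 1 with worker 1 only. Depth limits low features most in worker 1 (3 reads at the median length are 0.283 RPKM).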

Other observations

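The tests of adjacent numbers, of depth, of a single scaling factor, of loss with length, of library scaling and of the lone library were chosen after the results they measure, or closely related values, had been seen, while those of worker 2 alone and of neighbours after regression were set before. Features with adjacent ID numbers differed alike between the queen and the workers. Over 7299 adjacent pairs of tested numbered features, Pearson's r of the queen minus worker difference was 0.216, against at most 0.043 in 10000 shuffled orders (permutation p 0.0001, the smallest these shuffles can give). It was 0.10 at a distance of 2, 0.069 at 3, 0.043 at 5 and 0.012 at 10. Shared length and level of neighbours were argued against, since r was 0.223 after both were regressed out, with at most 0.050 in shuffled orders. A candidate explanation is that neighbours by number are neighbours on the chromosomes that change together, but the files do not say that numbers follow the genome, and gene models split over adjacent IDs would give the same pattern, so both stay open.

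Most features were lower in worker 1 than in worker 2 as deposited. The lower read total of worker 1 was argued against, because RPKM divides by that total. Over 1382 features with a mean of at least 30 RPKM the median log2 ratio was still -1.20 (95% bootstrap interval -1.30 to -1.12). The share of the read total in features with a recovered length also differed, at 18.9% in worker 1 and 37.5% in worker 2. Its part in the pattern was not tested and stays open. A single scaling factor for worker 1 as the whole cause was also argued against, since the median ratio differed by 1.31 (1.13 to 1.46) on the log2 scale between the shortest and longest features. Loss of signal that grows with length may be part of it, as Spearman's rho of length and ratio was -0.394 over 4558 features with a mean of at least 10 RPKM (permutation p 0.0001), and fragmented RNA could leave such a trend. A difference between a major and a minor worker stays open and untested, since 1 ant of each type was sequenced.

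More features were higher than lower in the queen as deposited. The low values of worker 1 could account for part of the excess. Against worker 2 alone, 1947 features were 4-fold higher and 789 lower in the queen, a share of 71.2%, which lies between the bounds of 60% and 80% set for and against this explanation. Library scaling and a broad rise of transcripts in the queen cannot be told apart, because the share of 39.2% after median-of-ratios scaling is largely fixed by its centring of the ratios.

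With 3 libraries there are only 3 choices of the lone library, too few for a share under 0.05. The choices are also unlike, since the spread that limma uses comes from the other 2 libraries. Pearson's r was 0.83 between the workers, but 0.48 between the queen and worker 1 and 0.47 between the queen and worker 2. The counts of calls are therefore not comparable between choices. The queen as the lone library gave 34 limma calls, the highest other choice, worker 1, gave 4, and worker 2 gave 0, so 1 of the 3 choices gave as many.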
